A study of Mus musculus with 5 samples.

How the data were processed

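Ventral skin of C57BL/6J mice at postnatal day 28 was dissociated and sorted to remove debris, dead cells positive for DAPI and aggregates, and captured with 10x 3' v2 chemistry, per the labels' protocols. Each library held the cells of 2 mice. There were 2 WT and 3 Ikkb_cKO libraries. The deposited matrices hold raw UMI counts per gene and cell barcode, whole numbers in a file per library. The reads were aligned and counted with Cell Ranger 1.3.0 against mm10, per the submitters' processing notes, while the matrices carry software version 3.0.1 and format version 2, per the file headers. The barcodes had already been called as cells, and the counting settings are not given in the sources used here. The matrices hold 31053 genes, of which 71 carry a symbol that stands on more than 1 line, each kept under its own identifier. Gene positions were taken from the GENCODE annotation of GRCm38.

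Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy, with an expected rate of 0.008 per 1000 cells, and 78 barcodes (0.704%) were removed as doublets. Of 11084 barcodes, 544 were removed in all. The rest were scaled to 10000 counts per cell, logged, and reduced to 2000 variable genes and 30 principal components without integration. A graph of 15 neighbours was cut by the Leiden method at resolution 1.0 into 32 clusters. Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 markers of a class among the 50 genes with the highest fold over the other clusters, with a lead of 2 over the next class, and no contradiction among the first 10. By this rule 30 clusters with 10469 cells were named, and 71 cells in 2 clusters stayed without a class. The classes are called fibroblast-like and so on, since no protein marker or sorting gate was used.

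UMI counts were summed per library and class, and classes with at least 20 cells in every library were tested. The libraries, not the cells, were the replicates. Genes passed edgeR's filterByExpr, were normalised by TMM, and were tested for Ikkb_cKO against WT with edgeR's robust quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. The share of each class was tested on cell counts by the same method with kept cells as the total, and by an exact permutation over the 10 splits of the libraries. Levels of Prrx1 and Ikbkb by class are plain CPM. Other levels, and those marked as on the normalised scale, are CPM normalised by TMM.

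The design, the tests, the gene lists, the cell-type markers, the alternatives and the rule for named genes were fixed before the data were examined. Of 33 gene lists, those with at least 5 tested members were compared with the other genes by camera in limma, with its preset correlation of 0.01 and with an estimated one. Limma's fry asked another question, whether the members of a list moved on balance one way, without reference to the other genes. Genes were named by this rule: Ikbkb, Prrx1 and Ccl11 always, then the 12 largest rises and 12 largest falls in fibroblast-like cells and 5 each in other classes, and up to 4 members per list with the smallest p. The ranked genes had to pass the threshold, with an average log2 CPM of at least 4 and no overlap between genotypes. Gene models, ribosomal protein, mitochondrially encoded, haemoglobin and sex-linked genes were left out of the ranking. In fibroblast-like cells 58 and 64 gene models and 20 and 33 ribosomal protein genes rose and fell. Genes with 1 to 3 UMIs in a genotype are given as a ratio of summed counts with a 95% counting interval.

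Alternatives were leaving out each library, DESeq2's size factors and its Wald test, limma's voom with quality weights, other low-count and cell filters (200 genes and 20%, 500 genes and 5%), no doublet removal, Leiden resolutions 0.5 and 2.0, variable genes without technical ones, equal cell numbers, and genes 10 times higher in another class left out. Summing alike libraries, and a test of whether the genotype effect differs between fibroblast-like and myeloid-like cells with library as a block, were added after the data were examined.

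The edgeR test was tested on simulated data with the spread of each class and 200 changed genes. In fibroblast-like cells it found 40% of 2-fold, 88% of 4-fold and 96% of 8-fold changes, with 4 false among 118 calls. With the spread drawn gene by gene these were 34%, 78% and 96%, and 15.4% of calls were false. In lymphocyte-like cells it found 18% of 2-fold and 74% of 4-fold changes. The simulated libraries were drawn independently and few genes were changed. In the data, pairs of libraries were alike and 3697 of 10469 fibroblast-like genes were called. These rates may therefore not hold for the real libraries. Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.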

Results

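Single-cell RNA sequencing (10x 3' chemistry) profiled ventral skin of C57BL/6J mice at postnatal day 28. There were 5 libraries, each from a pool of 2 mice. Of these, 2 came from wild-type animals (WT) and 3 from animals carrying Prx1Cre and floxed alleles of Ikkb (Ikkb_cKO). The gene, Ikbkb in current nomenclature, encodes the kinase IKKβ, which releases NF-kB from its inhibitors. The Cre is driven by an enhancer of Prrx1, a homeobox gene of limb and trunk mesenchyme. The title of the series places the question in fibroblasts: what loss of this kinase in the Prx1 lineage does to gene activity in the skin, in a setting of atopic dermatitis. The matrices held 3206 and 3393 barcodes in the WT libraries and 1017, 945 and 2523 in Ikkb_cKO libraries 1, 2 and 3. Total UMI counts were 14659158 and 16773096 in WT, and 2163166, 2350022 and 9738296 in Ikkb_cKO. After filtering, 10540 of 11084 barcodes remained, with median UMI counts per cell of 3607 and 4029 in WT and of 1607, 1883 and 2790 in Ikkb_cKO.

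The replicate libraries were compared before use. The shares of cell clusters differed between the WT libraries by a chi-square of 1.02 per degree of freedom, close to the value of independent draws from one suspension. Their summed fibroblast-like counts nevertheless differed more (5.36 per degree of freedom) than in any of 100 random splits of the pooled cells, of which the highest gave 3.73. For Ikkb_cKO libraries 1 and 2 the fibroblast-like counts gave 1.67, which 7 of 100 random splits equalled or exceeded, while the cluster shares gave 2.08 per degree of freedom. In lymphocyte-like cells 18 of 100 random splits equalled or exceeded the WT pair and 29 of 100 the pair of Ikkb_cKO libraries 1 and 2, so in that class neither pair stood apart from splits of a single pool. In myeloid-like cells only 2 of 100 did so for the WT pair and 1 of 100 for the other. All 5 libraries were kept as separate samples, as the labels give them. The p-values below measure the spread between these libraries, which may be technical.

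Lymphocyte-like cells made up a larger part of the Ikkb_cKO libraries. They were 3.94% ± 0.475 (SD, n = 2) of the cells in WT and 21.6% ± 2.04 (SD, n = 3) in Ikkb_cKO, a log2 difference of 2.46 (SE 0.33, adjusted p = 0.00751, edgeR's quasi-likelihood test on cell counts). The share was higher in 3 of 3 Ikkb_cKO libraries than in either WT library. With all libraries, the mesenchymal and myeloid classes did not differ past the threshold. Fibroblast-like cells were 58.7% ± 0.451 (SD, n = 2) of WT and 47.5% ± 9.32 (SD, n = 3) of Ikkb_cKO cells (log2 -0.30, adjusted p = 0.479 in edgeR), and myeloid-like cells were 26.8% ± 0.189 (SD, n = 2) and 18.0% ± 4.97 (SD, n = 3), with an adjusted p of 0.235 in edgeR. Mural-like cells, the pericytes and smooth muscle cells around vessels, were 1.78% ± 0.0172 (SD, n = 2) and 0.595% ± 0.316 (SD, n = 3), with an adjusted p of 0.159 in edgeR. Keratinocyte-like cells ranged from 0.917% to 12.96% within Ikkb_cKO, and the highest value was that of library 3. Without Ikkb_cKO library 3, lower shares passed for fibroblast-like (log2 -0.15, adjusted p = 0.0185), myeloid-like (-0.81, adjusted p = 0.00783), mural-like (-2.06, adjusted p = 0.00783) and endothelial-like cells (-1.26, adjusted p = 0.00783), and the mural-like share also passed under the stricter cell filter (adjusted p = 0.0494). In an exact two-sided permutation test of the 10 splits, the lymphocyte-like share gave p = 0.1, the smallest that 2 against 3 libraries allow. The call ended when WT library 1 was left out (log2 2.58, adjusted p = 0.192), when WT library 2 was left out (log2 2.34, adjusted p = 0.254), and when the cells were clustered without doublet removal (log2 1.75, adjusted p = 0.0933). It also ended under the looser cell filter (log2 1.74, adjusted p = 0.106) and at Leiden resolution 0.5 (log2 1.75, adjusted p = 0.0883). Digestion and droplet capture can set such shares, and 2 small clusters kept out of every class, led by immunoglobulin genes and by Ccl3, Ccl4 and Hdc, were 0.256% ± 0.0990 (SD, n = 2) of WT and 1.51% ± 0.577 (SD, n = 3) of Ikkb_cKO cells.

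**Figure D1:**
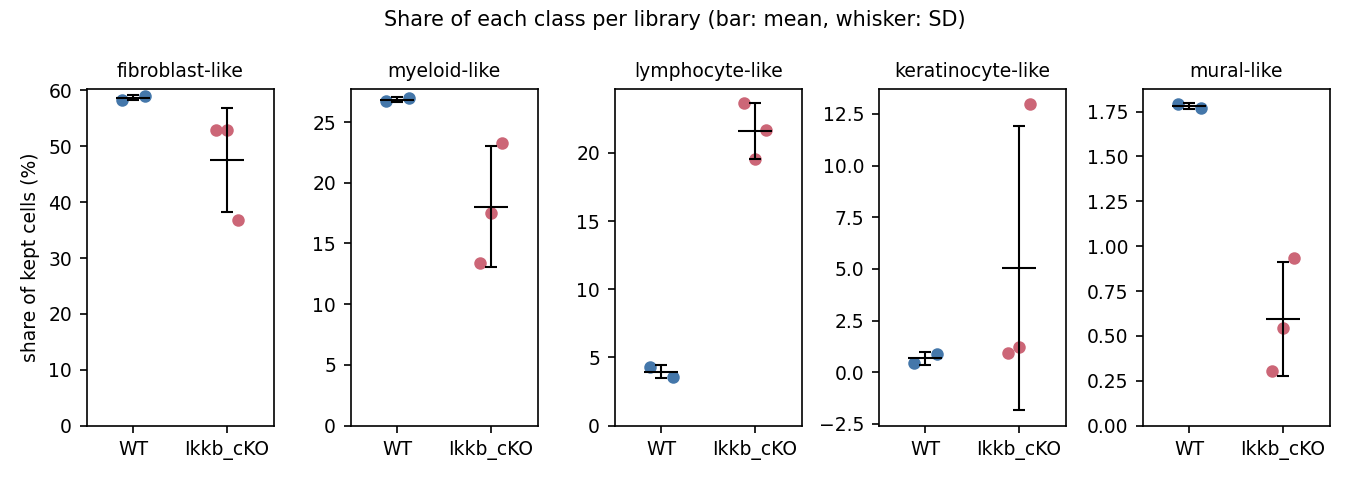
Share of kept cells (%, vertical axis, each panel with its own scale) of 5 classes in the 2 WT and 3 Ikkb_cKO libraries; points are libraries, bars the mean and whiskers the SD. Lymphocyte-like cells lie between 3.60% and 4.28% in WT and between 19.6% and 23.6% in Ikkb_cKO.

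Ikbkb itself, on chromosome 8 from 22659212 to 22706589 of the minus strand in GRCm38 (mm10), was detected alike in fibroblast-like cells of both genotypes. It had 16.4 ± 2.72 CPM (SD, n = 2) in WT and 17.6 ± 3.06 (SD, n = 3) in Ikkb_cKO, a log2 fold change of 0.05 (SE 0.22, adjusted p = 0.966 in edgeR). Its fitted sign turned in 4 of 21 alternative settings. The floxed exons are not given in the sources used here, and 3' tags of the transcript may lie outside them, so this level does not check the deletion. Myeloid-like cells held more of the transcript, at 101 ± 0.716 CPM (SD, n = 2) in WT and 146 ± 29.0 (SD, n = 3) in Ikkb_cKO.

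Prrx1 mRNA was found in the mesenchymal classes of WT skin. It reached 152 ± 2.22 CPM (SD, n = 2) in fibroblast-like and 155 ± 24.3 CPM (SD, n = 2) in mural-like cells, against 38.2 ± 15.7 (SD, n = 2) in Schwann-like and 25.0 ± 17.6 (SD, n = 2) in endothelial-like cells. Myeloid-like cells had 2.16 ± 0.156 CPM (SD, n = 2), and no UMI of it was seen in keratinocyte-like or lymphocyte-like cells of WT. A UMI was present in 51.4% ± 0.917 (SD, n = 2) of fibroblast-like cells, whose median depth was 4823 and 5331 UMIs, and in 0.594% ± 0.0249 (SD, n = 2) of myeloid-like cells, with 2564 and 2693.5 UMIs. With each cell thinned to 1000 UMIs the fibroblast-like share was 16.1% and the level 182 CPM. In Ikkb_cKO fibroblast-like cells Prrx1, at 163245119 to 163313710 on the minus strand of chromosome 1, rose from 155 ± 3.35 (SD, n = 2) to 294 ± 28.6 CPM (SD, n = 3) on the normalised scale, a log2 fold change of 0.92 (SE 0.14, adjusted p = 0.00462 in edgeR). Within fibroblast clusters Prrx1 was not past the threshold. It was at 0.3191 (SE 0.2229, adjusted p = 0.2691 in edgeR) in cluster 5 and at 1.057 (SE 0.3439, adjusted p = 0.06346) in cluster 21.

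The largest rise in fibroblast-like cells of Ikkb_cKO skin was in Col6a5, a chain of collagen VI, from 1.27 ± 0.132 CPM (SD, n = 2) to 1116 ± 718 (SD, n = 3), a log2 fold change of 9.74 (SE 1.12, adjusted p = 0.00343). Il6, the gene of interleukin-6, rose from 176 ± 7.67 CPM (SD, n = 2) to 753 ± 138 (SD, n = 3), a log2 fold change of 2.10 (SE 0.18, adjusted p = 0.00145). Ifit3, an interferon-induced antiviral gene, fell (log2 -3.62, SE 0.36, adjusted p = 0.00200). Tslp, which encodes an alarmin of type 2 inflammation, fell by 1.71 (SE 0.29, adjusted p = 0.00597), and Il33, which encodes another, rose by 2.03 (SE 0.37, adjusted p = 0.00933). All log2 values here are Ikkb_cKO over WT, and the adjusted p-values come from edgeR's quasi-likelihood test.

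Across 10469 genes tested in fibroblast-like cells, 1806 rose and 1891 fell, and 4885 had an unadjusted p under 0.05. Changes of more than 2-fold were 993 upward and 1088 downward. The 3 Ikkb_cKO libraries lay on one side of both WT libraries for 99.8% of the calls and for 60.8% of all genes tested. Chance gives 20% only if all libraries vary independently. The alike pairs among them put that in doubt, so the 60.8% cannot be read as an excess over chance. Different clusters held most of the class in the genotypes. WT cells lay mainly in clusters 3 (led by Clec3b), 2 (Fabp4 and Lum), 10 (Igfbp6) and 6 (Postn), and Ikkb_cKO cells in clusters 29 (Ptx3 and Col6a2), 21 (Col1a1 and Postn) and 0 (Col1a1 and Coch). Library 3 differed from the others here: cluster 29 held 61.5%, 60.7% and 12.2% of the class in Ikkb_cKO libraries 1, 2 and 3, and cluster 0 held 1.73%, 2.69% and 45.85%, against 4.75% and 5.11% in the WT libraries. The median UMI count of fibroblast-like cells was 5077 ± 359 (SD, n = 2) in WT and 1917 ± 474 (SD, n = 3) in Ikkb_cKO, whereas in lymphocyte-like cells it was 2197 ± 203 (SD, n = 2) and 2088 ± 422 (SD, n = 3).

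**Figure D2:**
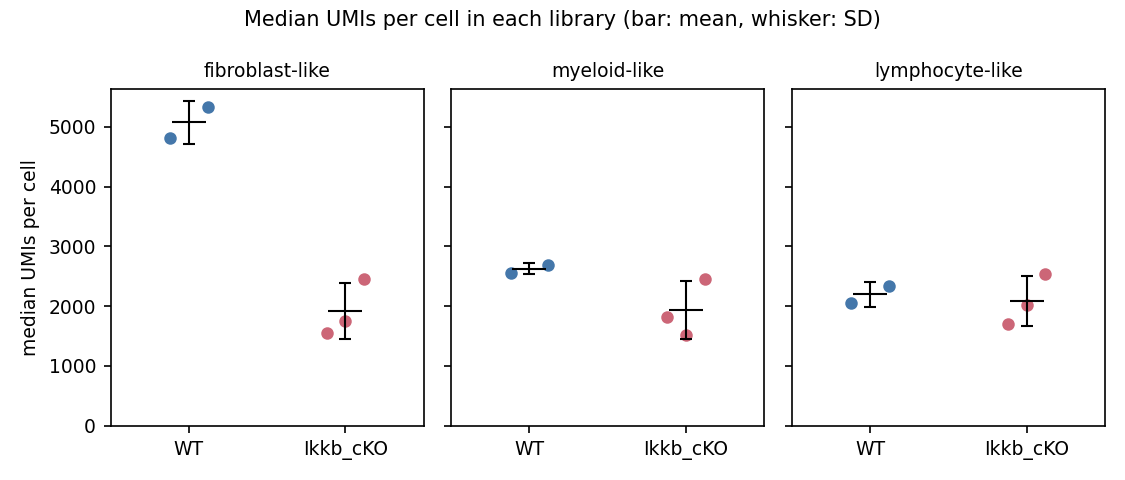
Median UMIs per cell (vertical axis) of fibroblast-like, myeloid-like and lymphocyte-like cells in each library; points are libraries, bars the mean and whiskers the SD of 2 WT and 3 Ikkb_cKO libraries. The fibroblast-like medians are 4823 and 5331 in WT and 1543, 1758 and 2450 in Ikkb_cKO.

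The other large rises in fibroblast-like cells included enzymes of signalling lipids and small molecules. Duox2, a hydrogen peroxide-producing oxidase, rose by a log2 fold change of 7.76 (SE 1.14). Ltc4s, the leukotriene C4 synthase, rose by 7.42 (SE 1.44), and Aldh1a2, a retinaldehyde dehydrogenase of retinoic acid synthesis, by 6.80 (SE 0.72). Car4, a membrane-bound carbonic anhydrase, rose by 6.74 (SE 0.87), Tdo2, which opens the ring of tryptophan, by 5.81 (SE 0.65), and Smpd3, a neutral sphingomyelinase, by 4.48 (SE 0.79). Receptors in this set were Mrgprg (6.06, SE 1.29), of the Mas-related family, and Csf2rb2 (5.44, SE 0.35), a beta chain of the interleukin-3 receptor. Susd4, a regulator of complement, rose by 5.25 (SE 0.97), Sel1l3 by 6.57 (SE 1.02) and Map3k7cl by 5.88 (SE 1.01). The adjusted p-values of these 11 genes ran from 0.00125 to 0.0184. Within cluster 21 Car4 rose by 4.371 (SE 0.7164, adjusted p = 0.00305 in edgeR). Ltc4s (1.036, SE 1.329, adjusted p = 0.6396) and Smpd3 (1.68, SE 0.7343, adjusted p = 0.1475) did not pass there. Cluster 29, with Smpd3 among its leading genes, held 0 and 1 cells in WT and 319, 294 and 106 in Ikkb_cKO. It could not be tested. Summed over libraries, Map3k7cl was 34.7 times and Csf2rb2 23.8 times higher in another class than in fibroblast-like cells.

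The largest falls took in secreted factors and cytoskeletal genes. Il34, a ligand of the CSF1 receptor on macrophages, fell by 4.12 (SE 0.30), Nes, the intermediate filament nestin, by 5.17 (SE 0.35) and Map2, a microtubule-associated protein, by 4.51 (SE 0.42). Nxph3, a neurexophilin (-5.53, SE 0.30), Crispld1 (-4.14, SE 0.31), Ldhb, a subunit of lactate dehydrogenase (-4.34, SE 0.37), and Akr1c18, a steroid-metabolising aldo-keto reductase (-3.75, SE 0.55), fell too. The adjusted p-values of these 7 genes ran from 0.00125 to 0.00591. Ccl12, a monocyte-attracting chemokine, had 970 UMIs in WT and 1 in Ikkb_cKO, a ratio of 202 (95% counting interval 36.2 to 8000). Tnfrsf18, the receptor GITR, had 716 and 1, a ratio of 149 (26.7 to 5910). Myh4, a fast muscle myosin, had 685 and 1, a ratio of 143 (25.6 to 5650), and was 107 times higher in muscle-like than in fibroblast-like cells. Car3, another muscle-abundant gene, fell by 3.61 (SE 1.05, adjusted p = 0.0452) and was 74.4 times higher in muscle-like cells. Ccl11, the eosinophil chemokine eotaxin, on the plus strand of chromosome 11 from 82057823 to 82062955, had 689 ± 34.9 CPM (SD, n = 2) in WT and 1083 ± 330 (SD, n = 3) in Ikkb_cKO. Its log2 fold change of 0.65 (SE 0.27, adjusted p = 0.107) was not past the threshold. Within fibroblast clusters the directions differed. Ccl11 was at -0.71 (SE 0.33, adjusted p = 0.109 in edgeR) in cluster 5 and at 1.195 (SE 0.28, adjusted p = 0.017) in cluster 21.

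**Figure D3:**
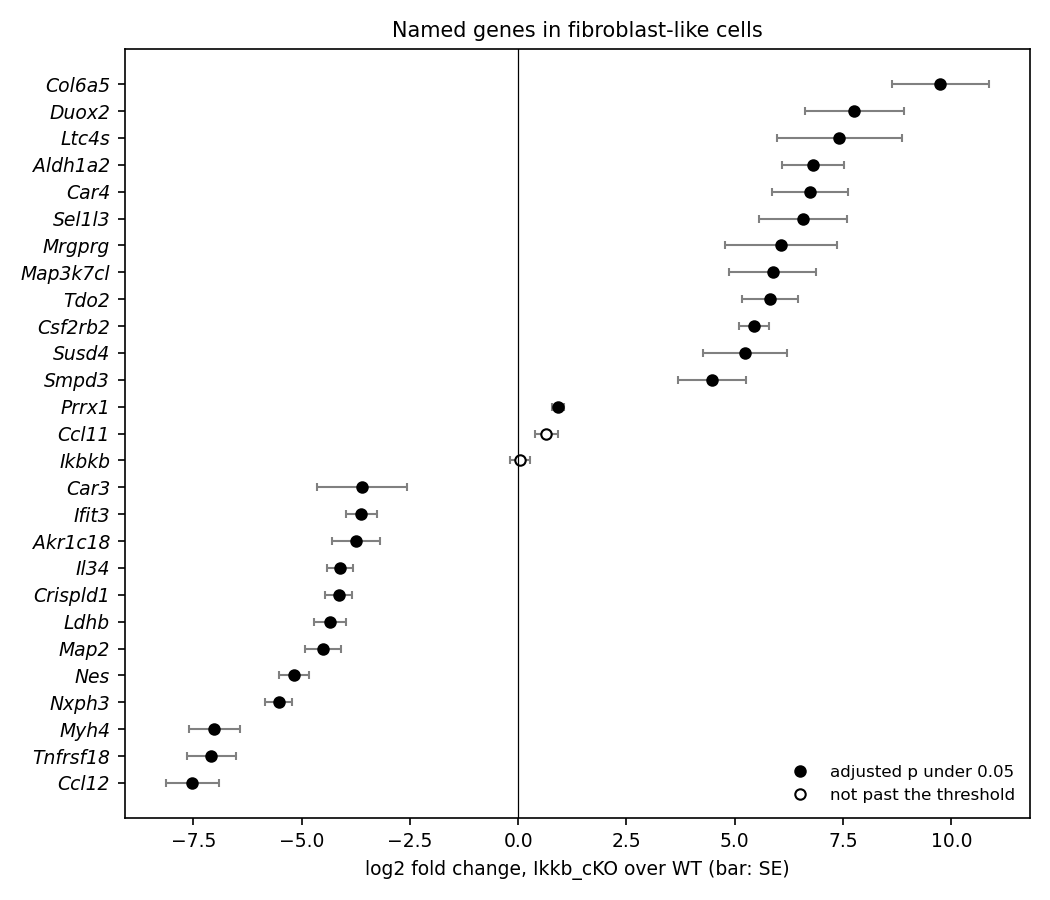
Log2 fold change (Ikkb_cKO over WT, horizontal axis) with its SE for 27 named genes (vertical axis) in fibroblast-like cells. Filled points are past the adjusted p threshold; Ccl11 (0.65) and Ikbkb (0.05), the open points, are not.

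Interferon-response genes were lower in Ikkb_cKO fibroblast-like cells: 20 of 35 measured members fell and 1 rose (24 and 1 adjusted over the list alone). Irf1, a transcription factor of the interferon response, fell by a log2 fold change of 1.61 (SE 0.13), Rtp4 by 1.96 (SE 0.17), the antiviral membrane protein gene Ifitm3 by 1.66 (SE 0.15) and Bst2, which encodes tetherin, by 1.83 (SE 0.17). Against other genes the list gave an adjusted p = 7.69e-08 in camera with its preset correlation and an adjusted p = 0.412 with an estimated correlation. Cell-cycle genes were lower too: 15 of 29 fell and 1 rose (15 and 1 adjusted over the list alone), among them the mitotic cyclin Ccnb2 (-2.56, SE 0.24), Cdk1 (-2.15, SE 0.30), the thymidylate synthase gene Tyms (-2.86, SE 0.39) and Stmn1 (-2.05, SE 0.24), with an adjusted p of 5.09e-05 in camera and an adjusted p = 0.412 with an estimated correlation. The camera values are over 29 lists, of which 5 passed with the preset correlation. With an estimated one 0 passed, 1 had an unadjusted p under 0.05, and limma's fry, which asks whether a list moved on balance one way and not whether it did so more than other genes, called 14.

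Of components of the NF-kB pathway, several rose in Ikkb_cKO fibroblast-like cells. Of 25 measured, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with an adjusted p = 0.0118 in camera and an adjusted p = 0.412 with an estimated correlation. Without Ikkb_cKO library 3 the list did not pass. The receptor genes Tnfrsf1b, for TNF, and Il1r1, for interleukin-1, rose by log2 fold changes of 2.05 (SE 0.23) and 1.5003 (SE 0.19), and the kinase Map3k7 (TAK1) and its partner Tab2 by 1.14 (SE 0.17) and 1.26 (SE 0.18). Il1r1 also rose within clusters 5 and 21. Tab2 rose within cluster 5 (1.748, SE 0.3602, adjusted p = 0.003983 in edgeR). In cluster 21 Tab2 was at -0.81 (SE 0.4487, adjusted p = 0.2529), not past the threshold. NF-kB target genes went both ways: 8 of 31 rose and 4 fell (8 and 5 adjusted over the list alone), with an adjusted p = 0.709 in camera. Il6 was among those that rose. Cxcl10 (-2.07, SE 0.18), a chemokine for T cells, and Ccl2 (-1.09, SE 0.12), a chemokine for monocytes, were among those that fell. Neutrophil and monocyte chemokines likewise split, with 3 of 15 up and 5 down (3 and 6 adjusted over the list alone), and an adjusted p = 0.115 in camera.

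Genes of the response to interleukin-4 and interleukin-13 changed in both directions in fibroblast-like cells, with 8 of 17 up and 4 down (8 and 4 adjusted over the list alone), and an adjusted p of 0.0528 in camera did not pass. The list passed as higher without Ikkb_cKO library 1, 2 or 3, under the stricter low-count and cell filters, with equal cells and with 1 or both alike pairs summed. Cish, a feedback inhibitor of cytokine signalling, rose by a log2 fold change of 2.01 (SE 0.22), and Il13ra1, a chain of the interleukin-13 receptor, by 1.01 (SE 0.14). Il13ra2, the decoy receptor, had 3 UMIs in WT and 51 in Ikkb_cKO, a ratio of 81.5 (95% counting interval 26.4 to 408). The matrix glycoprotein gene Tnc (-1.4995, SE 0.23) and the protease inhibitor gene Timp1 (-1.27, SE 0.20) fell. Timp1 did not fall within cluster 5 (1.202, SE 0.1975) or cluster 21 (0.4691, SE 0.3127). Among the 9 measured type 2 lymphocyte genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with an adjusted p = 0.000809 in camera and an adjusted p = 0.412 with an estimated correlation. Il13 and Gata3 of this list were 2491 and 574 times higher in lymphocyte-like than in fibroblast-like cells, whereas Rora (1.46, SE 0.18) and Hlf (3.99, SE 0.50), both transcription factors, differed less between these classes, at 6.40 and 9.17 times. With genes 10 times higher in another class left out, fewer than 5 members remained and the list could not be tested. Mitochondrially encoded transcripts, a measure of cell quality, rose in 8 of 13 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0118 in camera, adjusted p = 0.412 with an estimated correlation). Genes of the dissociation and stress response rose in 12 of 39 and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0528 in camera), and passed without WT library 1, without Ikkb_cKO library 1 or 3, under both other low-count filters and both other cell filters, with equal cells and with 1 or both alike pairs summed. Transcripts of muscle, vessels and blood fell in 3 of 7 and rose in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0528 in camera), and passed as lower without Ikkb_cKO library 2 or 3, under the stricter low-count and cell filters, with equal cells and with Ikkb_cKO libraries 1 and 2 summed. The chemokines and alarmins of type 2 inflammation gave 3 up and 1 down of 9 (3 and 1 adjusted over the list alone; adjusted p = 0.243 in camera).

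With a single WT library the count of fibroblast-like calls was 460 (WT library 2 alone) or 465 (WT library 1 alone), and 54 or 55 of the 110 named genes tested then were no longer past the threshold. Summing both pairs of alike libraries, a choice made after the data were examined, leaves 1 WT against 2 Ikkb_cKO samples with 1 residual degree of freedom and so little power. It called 2 genes, both lower in Ikkb_cKO and neither among the 3697, so 0 of those calls were kept, while 1847 genes had an unadjusted p under 0.05.

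**Figure D4:**
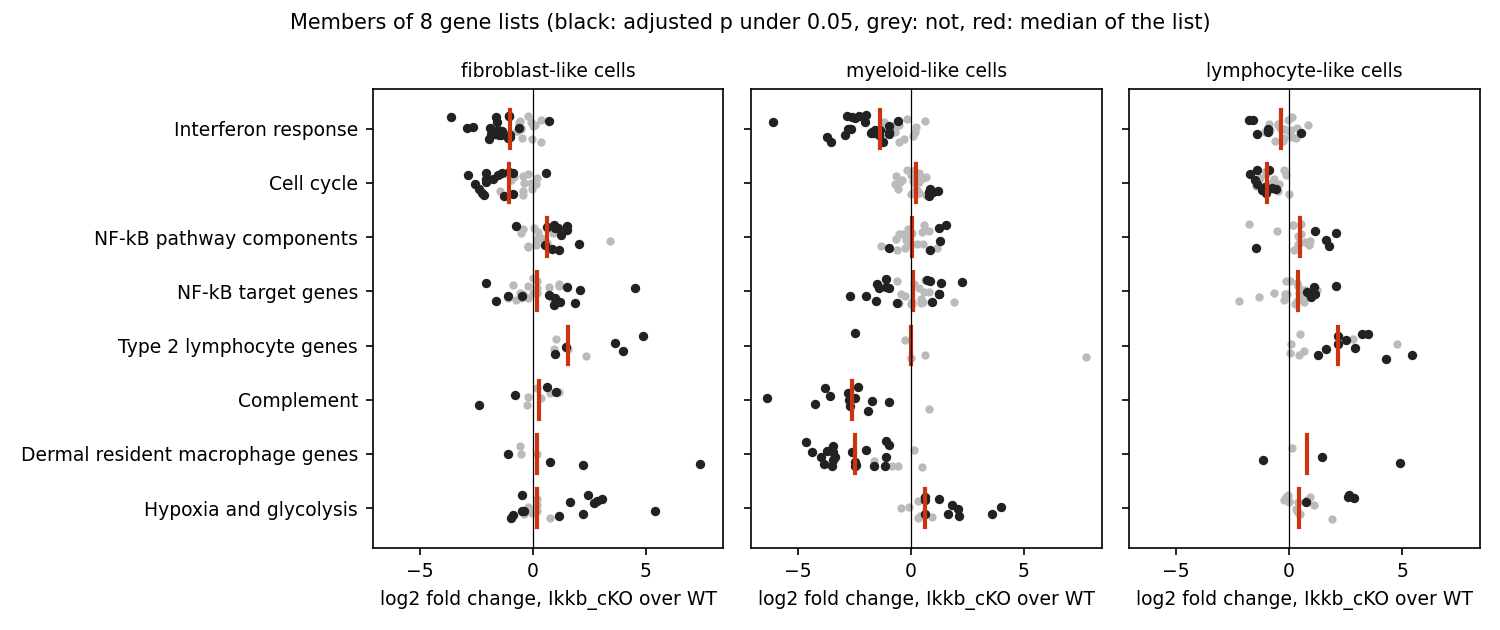
Log2 fold changes (Ikkb_cKO over WT, horizontal axis) of the measured members of 8 gene lists (vertical axis) in fibroblast-like, myeloid-like and lymphocyte-like cells. Each point is a gene, black where it passed the threshold, and red bars are list medians. Interferon-response members have medians of -1.03, -1.38 and -0.35 in the 3 classes.

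Myeloid-like cells of Ikkb_cKO skin had lower levels of genes that mark resident dermal macrophages, of complement and of the interferon response, and higher levels of genes of hypoxia and glycolysis. These list calls, made with a preset correlation, were lost with an estimated one, where the smallest was an adjusted p = 0.121. The C1q chains C1qa, C1qb and C1qc, which start the classical complement pathway, fell by log2 fold changes of 3.58 (SE 0.26), 3.80 (SE 0.25) and 4.24 (SE 0.28). Pf4, a chemokine gene abundant in tissue macrophages, fell from 2943 ± 312 CPM (SD, n = 2) to 185 ± 68.5 (SD, n = 3), by 3.98 (SE 0.26). Ccl17, a chemokine for type 2 T cells, rose from 6.50 ± 1.93 CPM (SD, n = 2) to 125 ± 52.9 (SD, n = 3), by 4.33 (SE 0.40), and Ccl22, which shares its receptor, by 2.22 (SE 0.40). The adjusted p-values of these genes lay between 2.60e-05 and 0.00382 in edgeR. Of 12 measured chemokines and alarmins of type 2 inflammation, Ccl17 and Ccl22 rose, while 5, among them Ccl24 and Tslp, fell (2 and 6 adjusted over the list alone). The list was lower, with an adjusted p = 0.0306 in camera and an adjusted p = 0.209 with an estimated correlation. Within myeloid clusters, however, Ccl24 did not fall. It rose by 3.897 (SE 0.5029, adjusted p = 0.001188 in edgeR) in cluster 7. In cluster 14 it was at 1.578 (SE 0.6055, adjusted p = 0.1667), not past the threshold.

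Of 8986 genes tested in myeloid-like cells, 778 rose and 858 fell, and 2904 had an unadjusted p under 0.05. The largest part of the class in WT lay in cluster 8, led by Pf4, C1qb and Retnla, with 47.6% ± 2.08 (SD, n = 2) of the class. In Ikkb_cKO cluster 8 held 13% ± 7.16 (SD, n = 3). In Ikkb_cKO the largest parts lay in clusters 14, led by Retnla and Cd74, with 46.5% ± 6.41 (SD, n = 3), and 7, led by Cd74 and H2-Aa, with 32.7% ± 8.85 (SD, n = 3). Of the largest rises, Rnase2a, an eosinophil-associated ribonuclease, rose by 4.71 (SE 0.49) and Scd2, a stearoyl-CoA desaturase, by 4.58 (SE 0.48). AA467197 had 1 UMI in WT and 127 in Ikkb_cKO, a ratio of 266 (95% counting interval 46.8 to 10600), and Plet1 had 1 and 157, a ratio of 328 (58.1 to 13000), with 39.6 times more in keratinocyte-like cells. Of the largest falls, Cd209f, a C-type lectin of macrophages, fell by 4.63 (SE 0.32) and Ccl12 by 4.46 (SE 0.27). Siglec1, the macrophage sialoadhesin, had 202 UMIs in WT and 3 in Ikkb_cKO, a ratio of 32.2 (10.9 to 157). Slc40a1, the iron exporter ferroportin, had 191 and 2, a ratio of 45.7 (12.5 to 380), and Ifit3 had 327 and 2, a ratio of 78.2 (21.5 to 648).

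Among lists in myeloid-like cells, 20 of 25 dermal resident macrophage genes fell and 0 rose (22 and 0 adjusted over the list alone), with an adjusted p = 1.4e-36 in camera and an adjusted p = 0.121 with an estimated correlation. Ltc4s (-3.50, SE 0.25), Fxyd2 (-3.43, SE 0.26) and Cd209f were examples. Complement genes fell in 13 of 14 and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 5.14e-21 in camera, adjusted p = 0.121 with an estimated correlation). Interferon-response genes fell in 24 of 37 and rose in 0 (28 and 0 adjusted over the list alone; adjusted p = 8.1e-22 in camera, adjusted p = 0.196 with an estimated correlation). Among them Isg15, a ubiquitin-like modifier, was at -2.60 (SE 0.19), Rtp4 at -3.56 (SE 0.28) and Oasl2 at -2.79 (SE 0.27). Hypoxia and glycolysis genes rose in 10 of 19 and fell in 0 (12 and 0 adjusted over the list alone; adjusted p = 7.68e-08 in camera, adjusted p = 0.129 with an estimated correlation), such as Vegfa (3.60, SE 0.37), Hk2 (2.15, SE 0.24) and Pfkp (1.81, SE 0.20), the latter pair enzymes of glycolysis. Macrophage inflammatory genes fell in 10 of 24 and rose in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.000880 in camera, adjusted p = 0.420 with an estimated correlation), with Tnf at -1.80 (SE 0.23) and Ccl2 at -2.70 (SE 0.31) among the falls.

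Genes of the interleukin-4 and interleukin-13 response split in myeloid-like cells, with 7 of 26 up and 6 down (9 and 7 adjusted over the list alone), and an adjusted p of 0.144 in camera did not pass, although it passed as higher without Ikkb_cKO library 2 and with 1 or both alike pairs summed. Chil3, a chitinase-like protein gene of alternatively activated macrophages, rose by 3.87 (SE 0.44) and Cish by 3.16 (SE 0.34). Clec10a, a lectin of the same macrophage state, fell by 1.62 (SE 0.17). Transcripts of fibroblasts in myeloid-like cells fell in 12 of 16 and rose in 0 (13 and 1 adjusted over the list alone; adjusted p = 3.91e-10 in camera, adjusted p = 0.209 with an estimated correlation). Of these, Col3a1 (-1.91, SE 0.25) was 116 times and Sparc (-2.70, SE 0.27) 98.5 times higher in fibroblast-like cells. Transcripts of muscle, vessels and blood fell in 3 of 5 and rose in 0 (4 and 1 adjusted over the list alone; adjusted p = 0.0115 in camera, adjusted p = 0.209 with an estimated correlation). Mitochondrially encoded transcripts rose in 5 of 13 and fell in 0 (5 and 1 adjusted over the list alone; adjusted p = 0.0939 in camera), and the median mitochondrial share of these cells was 2.27% and 2.33% in WT and 3.10%, 2.65% and 3.17% in Ikkb_cKO. With the preset correlation 13 of 27 lists passed in this class and with an estimated one 0 did, although 5 had an unadjusted p under 0.05 and fry called 11. Leaving out WT library 1 or 2 gave 434 or 440 calls, and 26 of 90 named genes lost theirs in each. Calls fell to 677 when both alike pairs were summed, to 834 with DESeq2 and to 767 with equal numbers of cells per library.

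Lymphocyte-like cells of Ikkb_cKO skin had more mRNA of type 2 lymphocyte genes and less of cell-cycle genes, list calls that were lost with an estimated correlation (adjusted p = 0.222 and adjusted p = 0.351). Gata3, the transcription factor of type 2 lymphocytes, rose from 184 ± 1.72 CPM (SD, n = 2) to 814 ± 238 (SD, n = 3), a log2 fold change of 2.14 (SE 0.25, adjusted p = 0.000314 in edgeR). Il5, the eosinophil growth factor, rose by 2.52 (SE 0.46, adjusted p = 0.0320), and Areg, the epidermal growth factor-like amphiregulin, by 2.92 (SE 0.51, adjusted p = 0.0409), calls that were both lost when either WT library was left out. Il4 had 1 UMI in WT and 179 in Ikkb_cKO, a ratio of 48.3 (95% counting interval 8.56 to 1920). Nkg7, a granule protein gene of cytotoxic cells, fell by 1.00 (SE 0.15, adjusted p = 0.00122), and Gzmk, a granzyme, by 5.08 (SE 0.64, adjusted p = 0.000793). Within the cluster led by Areg, Il13 and Il5, however, Nkg7 rose by 2.20 (SE 0.61, adjusted p = 0.0289 in edgeR).

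Of 5162 genes tested in lymphocyte-like cells, 358 rose and 239 fell, and 1465 had an unadjusted p under 0.05. Cluster 11, led by Ccl5, Gzmc and Nkg7, held 44.6% ± 1.54 (SD, n = 2) of the class in WT, and cluster 12, led by Areg, Il13 and Il5, held 52.2% ± 12.2 (SD, n = 3) in Ikkb_cKO. Bcar3 had 0 UMIs in WT and 54 in Ikkb_cKO, at least 4.85-fold higher with 3 counts over the WT group as floor. Il1r2, the interleukin-1 decoy receptor, had 3 and 783 UMIs, a ratio of 70.4 (24.0 to 342), Nlrp3, an inflammasome sensor, had 1 and 264, a ratio of 71.2 (12.7 to 2820), and Serinc5 had 1 and 123, a ratio of 33.2 (5.85 to 1320). Tmem176b fell by 3.41 (SE 0.28) and Gclm, a subunit of the enzyme that limits glutathione synthesis, by 2.85 (SE 0.32). The T cell receptor segments Trbv17 (-4.80, SE 0.70) and Trbv13-1 (-4.74, SE 0.40) also fell, and such near-identical family members can share tags.

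The type 2 lymphocyte list rose in 10 of 17 members and fell in 0 (13 and 0 adjusted over the list alone), with an adjusted p = 1.02e-18 in camera and an adjusted p = 0.222 with an estimated correlation. Beside Gata3 it included Hlf (4.29, SE 0.41) and Rora (1.29, SE 0.19), transcription factors of innate lymphocytes. Of type 1, type 17 and regulatory lymphocyte genes, 4 of 20 fell and 2 rose (4 and 2 adjusted over the list alone; adjusted p = 0.0330 in camera, adjusted p = 0.334 with an estimated correlation), with Cxcr3, a chemokine receptor of type 1 cells, at -2.16 (SE 0.34) and Il2ra at 1.62 (SE 0.26). Cell-cycle genes fell in 10 of 24 and rose in 0 (14 and 0 adjusted over the list alone; adjusted p = 6.25e-08 in camera, adjusted p = 0.351 with an estimated correlation), such as Ube2c (-1.41, SE 0.29) and Mcm5 (-1.53, SE 0.42). NF-kB target genes rose in 5 of 24 and fell in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.0330 in camera, adjusted p = 0.334 with an estimated correlation), among them Nfkb1 (2.06, SE 0.21) and Tnfaip3 (0.97, SE 0.16). Interferon-response genes fell in 5 of 24 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0226 in camera, adjusted p = 0.468 with an estimated correlation). Cells of this class thinned to 1000 UMIs held 12.79 ± 0.501 (SD, n = 2) UMIs of the list in WT and 12.47 ± 0.664 (SD, n = 3) in Ikkb_cKO. Mitochondrially encoded transcripts, a measure of cell quality, rose in 9 of 13 and fell in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.00125 in camera, adjusted p = 0.380 with an estimated correlation). Transcripts of fibroblasts rose in 2 of 7 and fell in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0144 in camera, adjusted p = 0.398 with an estimated correlation), and the 2, Dcn (1.48, SE 0.41) and Gsn (1.57, SE 0.45), turned in sign when doublets were kept (-0.73 and -3.01). Of 19 lists 15 passed with the preset correlation, and 4 did under the looser cell filter, without doublet removal or at Leiden resolution 0.5, and 7 with equal cells. The interferon call was lost in each of these settings, under the stricter cell filter, with genes 10 times higher in another class left out and without WT library 1 or Ikkb_cKO library 3, that of NF-kB targets in the first 3, with both alike pairs summed and without WT library 2, and that of type 1, type 17 and regulatory genes in the same first 3, with equal cells, under the stricter cell filter and without Ikkb_cKO library 1 or 3. With an estimated correlation 0 of 19 lists passed, 2 had an unadjusted p under 0.05 and fry called 6.

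The lymphocyte-like count rested on single libraries. It was 142 and 83 without WT libraries 1 and 2, and 319, 307 and 1151 without Ikkb_cKO libraries 1, 2 and 3. DESeq2 called 318 genes. Where the cluster led by Il5 and Il13 dropped out of the class, under the looser cell filter, without doublet removal and at Leiden resolution 0.5, the counts were 209, 201 and 211. Of 62 named genes of this class, 36 and 45 lost their call without WT libraries 1 and 2, and of the 50 tested in the 3 settings without that cluster 25, 20 and 24 did, with 1, 5 and 1 more turned in sign. Summing Ikkb_cKO libraries 1 and 2 gave 275 calls, and summing both alike pairs, a test of little power with 1 WT sample left, gave 5.

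Keratinocyte-like, endothelial-like and mural-like cells numbered 9, 9 and 3 in their smallest library, below the minimum of 20, and were not tested for changed genes. The planned comparison of the genotype effect between fibroblast-like and keratinocyte-like cells was not run for the same reason.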

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

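The genotype effect was compared between fibroblast-like and myeloid-like cells, a test chosen after the results in each class were seen. It was past the threshold for 1337 of 11454 genes, of which 862 had the higher log2 fold change in fibroblast-like cells. With genes 10 times higher in another class left out, 755 were higher and 754 lower in fibroblast-like cells, so this lean was not kept. Of 690 genes that passed in both classes, 619 went the same way and 71 the opposite way, and for 70 of these the difference itself passed. A call each way in the separate tests makes a passing difference likely, so the 70 are no separate evidence. The 5 with the smallest p among these 70 are given here, and their opposite effects follow from that choice. Acot7, an acyl-CoA thioesterase, fell in fibroblast-like cells (log2 -2.19) and rose in myeloid-like cells (1.59), a difference of -3.65. The others rose in fibroblast-like and fell in myeloid-like cells: Ighm, the immunoglobulin mu chain (2.40 and -0.98, difference 3.39, and a leading gene of a cluster without a class that held 10 and 6 cells in WT and 15, 14 and 15 in Ikkb_cKO, whose free RNA was not excluded as its source), Sash1 (1.31 and -1.97, difference 3.30), Man1c1, a mannosidase (1.40 and -1.33, difference 2.88), and Cmah, an enzyme of sialic acid (1.51 and -2.61, difference 3.84). Other genes were singled out after their values were seen. Timp1 fell by 1.27 in fibroblast-like cells and rose by 2.56 in myeloid-like cells, a difference of -3.71 (SE 0.40). Within fibroblast clusters, however, Timp1 did not fall. It rose by 1.202 (SE 0.1975, adjusted p = 0.00155 in edgeR) in cluster 5. In cluster 21 it was at 0.4691 (SE 0.3127, adjusted p = 0.3307), not past the threshold. The genotypes hold different fibroblast clusters, so the opposite effect of Timp1 holds for the class as a whole only. The complement gene C4b rose by 1.05 in fibroblast-like and fell by 2.69 in myeloid-like cells, a difference of 3.63 (SE 0.33). Within clusters C4b kept these directions but did not pass. It was at -1.226 (SE 0.5448, adjusted p = 0.1465 in edgeR) in myeloid cluster 14. In fibroblast clusters 5 and 21 it was at 1.305 (SE 0.522) and 2.276 (SE 0.6851). The count was 445 and 414 without WT libraries 1 and 2, 870 without Ikkb_cKO library 2, and 538 with equal cell numbers. No cause was tested for these differences.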

How the results depend on the processing

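In fibroblast-like cells the count of 3697 changed genes became 460 and 465 without WT libraries 1 and 2, and 5455 without Ikkb_cKO library 3. With a single WT library, that library is assumed to vary like the Ikkb_cKO libraries. It was 2 with both alike pairs summed, which leaves 1 residual degree of freedom (1847 at an unadjusted p under 0.05), and lay between 2865 and 5030 in every other setting. No changed gene turned in sign in any setting. Without the low-count filter 40.1% of the calls were rises, against 48.9%. The 1636 myeloid-like calls became 434 and 440 without WT libraries 1 and 2 and 1820 without Ikkb_cKO library 1, 834 with DESeq2's Wald test, 767 with equal cells and 677 with both alike pairs summed. The 597 lymphocyte-like calls became 142 and 83 without WT libraries 1 and 2, and 319, 307 and 1151 without Ikkb_cKO libraries 1, 2 and 3. They became 318 with DESeq2's Wald test, 209 with the looser cell filter, 201 without doublet removal, 211 at Leiden resolution 0.5, 275 with Ikkb_cKO 1 and 2 summed and 5 with both alike pairs summed (964 at an unadjusted p under 0.05). The difference between fibroblast-like and myeloid-like cells, past for 1337 genes, was so for 445 and 414 without WT libraries 1 and 2, 870 and 1727 without Ikkb_cKO libraries 2 and 3, and 538 with equal cells.

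Of gene lists in fibroblast-like cells, 5 passed in camera with the preset correlation. This was 8 and 5 without WT libraries 1 and 2, 9, 9 and 10 without Ikkb_cKO libraries 1, 2 and 3, 9 with the stricter low-count filter, 8 with the stricter cell filter, 9 with equal cells, 10 with Ikkb_cKO 1 and 2 summed and 9 with both alike pairs summed. With an estimated correlation it was 0 in each. Of class shares, 1 passed (2 at an unadjusted p under 0.05). This was 0 without WT library 1 or 2 (1 unadjusted each), 2 and 5 (endothelial-like, fibroblast-like, lymphocyte-like, mural-like and myeloid-like) without Ikkb_cKO libraries 2 and 3, 2 with the stricter cell filter, and 0 with the looser filter, without doublet removal and at Leiden resolution 0.5 (2 unadjusted each, edgeR). The lymphocyte-like share, at log2 2.46, was 2.58 and 2.34 without WT libraries 1 and 2, and 1.74, 1.75 and 1.75 in the last 3 settings, where the cluster led by Il5 and Il13 had no class. Prrx1 in WT fibroblast-like cells was 181.8 CPM with a UMI in 16.07% of cells thinned to 1000 UMIs.

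Ikbkb in fibroblast-like cells, not past the threshold, turned to -0.1175 without WT library 1, -0.06149 without Ikkb_cKO library 2, -0.04996 without the low-count filter and -0.07597 with the stricter cell filter, and was 0.2112 without WT library 2. In lymphocyte-like cells without doublet removal, Dcn turned to -0.7288, Plin2 to -0.1243, Gadd45b to -0.01555, Gsn to -3.01 and Fcer1g to 0.0665. Fcer1g in lymphocyte-like cells turned to 0.005103 with the looser filter and 0.01708 at Leiden resolution 0.5. The cause was not tested.

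Same-numbered libraries deviated with correlations from -0.0509 to 0.0357. With 2 WT libraries, their deviations from the WT mean are mirror images. These values therefore cannot tell whether the replicate numbers pair the samples. With the replicate block 1312 lymphocyte-like genes, 5030 fibroblast-like genes, 8 fibroblast-like lists (without that of NF-kB pathway components and with those of the interleukin-4 and interleukin-13 response, the stress response and vessel, muscle and blood RNA; in lymphocyte-like cells this list, the interferon list and the type 1, type 17 and regulatory list were lost) and 5 class shares (endothelial-like, granulocyte-like, lymphocyte-like, mural-like and myeloid-like) passed, and Slpi in myeloid-like cells turned from 2.45 to -0.02155. The planned tests of keratinocyte-like, endothelial-like and mural-like cells were not run.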

Other observations

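Markers of dermal layers changed in both directions in fibroblast-like cells. Among papillary markers 1 of 14 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.709 in camera): the Wnt inhibitor Wif1 rose by a log2 fold change of 3.52 (SE 0.77), and the secreted Wnt modulator Sfrp4 (-1.69, SE 0.22) and the collagens Col18a1 (-1.93, SE 0.37) and Col13a1 (-1.72, SE 0.46) fell. Among reticular and fascia markers 3 of 22 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.879 in camera), with Dpt (0.78, SE 0.11) up and Cd248 (-1.38, SE 0.12) down. Of adipogenic genes 3 of 17 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.879 in camera), with the transcription factor genes Cebpb (2.64, SE 0.31) and Pparg (-1.85, SE 0.30) apart. Of matrix genes 6 of 35 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.879 in camera).

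All tests of explanations for the lower interferon genes, and the test of library depth below, were chosen after the result was seen. Fibroblast-like cells of Ikkb_cKO libraries held fewer UMIs, at 0.378 times the WT mean of medians. Lower depth of whole libraries does not explain this, since the ratio of fibroblast-like to lymphocyte-like medians was 2.53 times higher in WT. Cells with a high mitochondrial share do not account for it either, as those with at most 2.5% mitochondrial UMIs gave a ratio of 0.298. These were 1235 and 1277 cells in the WT libraries and 86, 97 and 198 in the Ikkb_cKO libraries. Damage that leaves the mitochondrial share low was not tested. A loss of the clusters with the most UMIs cannot be told apart from a change within cells: the ratio was 0.366 in cluster 5 and 1.53 in cluster 21. A biological change of the cells themselves, in the genotype, may remain, and its cause was not tested.

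Interferon-response genes were lower in fibroblast-like and myeloid-like cells. Fewer UMIs per cell do not explain it, because cells thinned to 1000 UMIs held 1.94 times more of these UMIs in WT fibroblast-like and 2.16 times more in WT myeloid-like cells, against 1.03 times in lymphocyte-like cells. Within myeloid clusters 7 and 14 the list median was -1.38 or lower, so a different mix of clusters does not account for the fall inside them. Cluster 8, with 47.6% of the WT class, held 8 cells in Ikkb_cKO library 1 and was not tested. A part of the mix in the fall of the whole class was therefore not excluded. The prediction on cluster mix was split by class after the values were seen. As a single prediction its outcome was open for both classes. For fibroblast clusters the mix cannot be told apart from a change within cells, with medians of -1.53 in cluster 5 and -0.104 in cluster 21, where 7 members were tested. An effect of genotype could account for the rest, but the labels name no batches, and a batch that runs with genotype could do the same.

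Fibroblast-like cells of Ikkb_cKO library 3 stood apart from libraries 1 and 2, with a mean correlation of 0.9085 against 0.9655 between those. Without cluster 0, which library 3 fills most, it was 0.932, which lies between the outcomes foreseen, so this explanation stays open. That rests on a rounding: the bound for excluding it was first written slightly higher and shortened before the test was run, and the first bound would have excluded it. Without genes 10 times higher in another class the correlation was 0.916, so free RNA of those genes does not account for the difference. Free RNA of genes that differ less between classes was not tested. No biological explanation was tested.

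A hypothesis was tested that type 2 genes are higher in Ikkb_cKO lymphocyte-like cells only because the cluster led by Il5 and Il13 is larger, with the test chosen after the result was seen. Within that cluster 8 of 19 tested members rose, among them Areg, Il5, Il13 and Gata3, and 2, Csf2 and Ccr8, fell. These 8 rises go against a larger cluster made of the same cells. The cluster was drawn from the same data, however, is led by several of these genes, and held only 26 and 27 WT cells. A different mix of cells inside it was therefore not excluded.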
